A study of Escherichia coli K-12 with 15 samples.

How the data were processed

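The study covers RNA from E. coli K-12 in 5 groups of 3 libraries: WT, an hns knockout (KO), and knockout strains that carry a gene for wild-type H-NS (KO+wtHNS), K121Q H-NS (KO+K121Q) or K121R H-NS (KO+K121R). Per the labels, cells grew in LB at 37 °C to an OD of 0.6 and were then kept in LB at pH 2.5 for 2 h. RNA was taken with Trizol and sequenced from TruSeq RNA libraries. All 15 libraries are acid stressed and no unstressed sample was analysed here, so every difference is between strains under acid. The values deposited by the authors hold 1 number per gene and library, without a named unit, and on testing they are RPKM. Multiplied by gene length they sum to about the same total in each library, and 96.8 to 97.3% of non-zero values are whole multiples of 1 step per library within 0.05. Whether single reads or fragments were counted, the strand of counting and the aligner are not given in the sources used here. The labels give the build ASM584v2. Of 4497 identifiers, 4487 matched its gene table and supplied symbols, coordinates and lengths.

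The step of each library corresponds to between 3134802 and 3966168 assigned reads, and between 88 and 210 genes per library are at 0. Reads recovered in this way were used for an alternative test and for genes near 0, and such counts cover counting error only. A few transcripts take large shares: 19 genes exceed 1% of reads in some library, and ssrA holds between 6.80 and 29.0% of reads, most in KO+wtHNS replicate 3.

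Values were analysed in R 4.3.3 with limma 3.58.1. RPKM values were taken as log2(value + 1), genes with a value of at least 1 in at least 3 libraries were kept (4436 genes), and all 15 libraries entered 1 fit by limma-trend with robust variance moderation. The counting tools edgeR and DESeq2 were not used, because the values are not counts. Adjusted p-values are Benjamini-Hochberg over the tested genes within each comparison, and genes under 0.05 are called. The 6 comparisons were KO against WT, KO+wtHNS against KO, KO+wtHNS against WT, KO+K121Q against KO+wtHNS, KO+K121R against KO+wtHNS, and KO+K121Q against KO+K121R. Library titles carry replicate numbers, and the fit did not treat these as pairs. Deviations from the group means of libraries with the same number correlated above 0.1 in all 3 cases for KO+wtHNS with KO+K121Q (0.126, 0.218 and 0.161) and for KO with KO+K121R (0.116, 0.155 and 0.326), and not for the other 8 pairs of groups. For these 2 the numbers were read as possible pairs, and a fit with the number as a block is given where it changes a call.

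Gene lists were 22: the acid fitness island, glutamate-dependent acid resistance, arginine, lysine and ornithine acid resistance, EvgAS, YdeO and PhoPQ acid signalling, H-NS silenced loci, nucleoid-associated proteins, flagella and chemotaxis, curli, type 1 fimbriae, colanic acid capsule, RpoS-dependent general stress, heat shock, envelope stress, the SOS response, ribosomal proteins, the TCA cycle, ATP synthase, the maltose regulon, lipopolysaccharide core, cryptic prophages, iron acquisition and rRNA genes. They were written from general knowledge of E. coli. Of these, 21 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera compares the genes of a list with all other genes, while fry asks whether the genes of a list move on balance in 1 direction. Their p-values were adjusted over the 21 lists. The acid fitness island and the glutamate list share 4 genes, and the silenced loci and the nucleoid-associated proteins share stpA.

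Genes were named by a rule. From each comparison it takes, among called genes whose libraries do not overlap and with a mean of at least 10 RPKM in either group, the 10 with the largest and the 10 with the smallest log2 change. It adds the 4 called members with the largest absolute change from each list past camera, and a fixed set whatever its result: hns, stpA, hha, leuO, bglG, proV, gadA, gadB, gadC, gadE, gadX, gadW, hdeA, hdeB, hdeD, slp, mdtE, adiA, adiC, cadA, cadB, asr, cfa, evgA, ydeO, ydeP, rpoS, rcsB, tmcA, flhD, fliC, csgA, csgD and fimA. The groups, the comparisons, the test, the lists, the naming rule and most alternatives were chosen before the data were examined. A transcript that overlaps another or has a close paralog, such as gadA and gadB, has an uncertain value.

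Alternatives were no filter on low values, only the 6 libraries compared, the replicate number as a block, omission of the genes over 1% of reads, calls of at least 2-fold, a pseudocount of 0.1, quantile normalization, moderation that is not robust, and omission of each library in turn. Chosen after the data were seen were limma-voom on recovered reads, median scaling (each library shifted so that its median log2 value over tested genes is the same), WT in place of KO+wtHNS as the reference, and the 4 comparisons of KO+K121Q and KO+K121R with WT and KO. Limma-voom scaled each library by the median ratio of its reads to the geometric mean over libraries, whereas RPKM values are scaled to all assigned reads. On simulated data with 100 genes changed 2-fold and 100 changed 4-fold, limma-trend recovered 31% and 76% with 5 false calls in the setting of KO against WT, and 27% and 82% with 3 false calls in that of KO+K121R against KO+wtHNS. All other simulated genes had the same mean in every group, and as many genes were raised as lowered. These rates therefore do not cover the many calls or the shift in scaling seen between the real groups. In 20 simulated runs camera called the changed list in 20 and an unchanged list in 0, with either correlation. The simulated genes varied independently of each other, so these runs do not cover lists of genes that move together.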

Results

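Transcript levels were compared between 5 groups of acid-stressed E. coli K-12 with 3 libraries each. These were wild type (WT), a strain without the nucleoid protein H-NS (KO), and 3 knockout strains with an added hns gene. The added gene encoded wild-type H-NS (KO+wtHNS), H-NS with glutamine at a lysine (KO+K121Q) or H-NS with arginine at that lysine (KO+K121R). H-NS binds AT-rich DNA and silences many genes gained by horizontal transfer. Glutamine and arginine at a lysine are common stand-ins for its acetylated and unacetylated forms. Values are group means in RPKM, reads per kilobase of gene scaled to the reads assigned in each library, ± SD over the libraries of a group (n = 3). Log2 changes are ± SE of the fit. Genes are called higher or lower at an adjusted p under 0.05 of limma's test. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure only the spread between these libraries. Where a list had 5 or fewer calls in 1 direction, those genes are named even if the naming rule did not pick them, chosen after their values were seen.

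The hns gene (b1237, 1292509 to 1292922 of ASM584v2) gave 6212, 3541 and 5005 RPKM in the WT libraries and 0, 0 and 0.772 RPKM in the KO libraries. It gave 3857, 2791 and 5195 RPKM in KO+wtHNS, 14150, 16840 and 11600 RPKM in KO+K121Q, and 3503, 4018 and 5631 RPKM in KO+K121R. The hns transcript was higher in KO+K121Q than in KO+wtHNS (log2 change 1.88 ± 0.33, adjusted p = 0.00140) and than in KO+K121R (1.71 ± 0.33, adjusted p = 0.00316). It was not called different between KO+wtHNS and WT (adjusted p = 0.759). Gene-level values do not show the sequence of hns, so the form of H-NS in each group is as the labels give it. Across tested genes, which are not independent replicates, the mean correlation between libraries was 0.959 within WT, 0.821 between WT and KO, 0.936 between WT and KO+wtHNS, 0.902 between WT and KO+K121Q, and 0.940 between WT and KO+K121R.

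**Figure D1:**
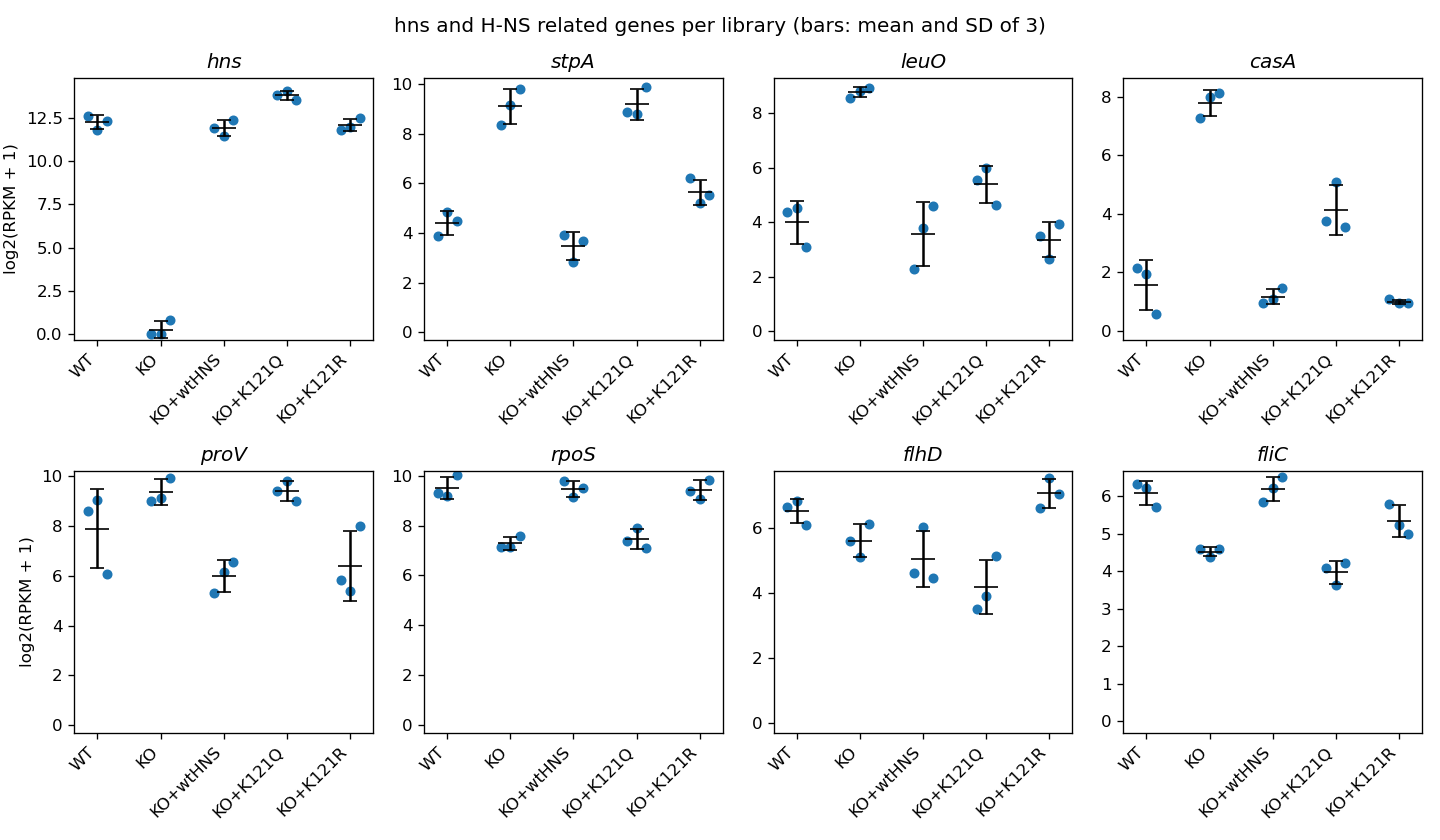
Each point is the log2(RPKM + 1) of 1 library, with the mean and SD of 3 libraries as bars, for hns and 7 genes named in the text in the 5 groups. The KO libraries hold between 0 and 0.772 RPKM of hns, and stpA is high in KO and KO+K121Q.

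Loss of H-NS under acid stress went with much higher transcripts of genes that H-NS is known to silence. The gene casA (b2760, 2882630 to 2884138), which encodes a part of the Cascade complex of the CRISPR system, rose from 2.27 ± 1.57 to 228 ± 64.8 RPKM (log2 change 6.23 ± 0.45, adjusted p = 8.21e-07), and casB rose from 5.11 ± 3.37 to 639.9 ± 178 RPKM (6.82 ± 0.71, adjusted p = 1.49e-05). Genes of H-NS relatives and of an H-NS antagonist rose as well. The transcript of stpA, whose product is a paralog of H-NS, went from 20.9 ± 7.02 to 595 ± 279.8 RPKM (4.71 ± 0.43, adjusted p = 4.44e-06). That of hha rose from 149.6 ± 69.2 to 1945 ± 499 RPKM (3.77 ± 0.47, adjusted p = 5.29e-05) and that of leuO from 16.4 ± 7.80 to 432 ± 53.8 RPKM (4.76 ± 0.56, adjusted p = 2.98e-05). The gene of the general stress sigma factor, rpoS, fell from 750.3 ± 248 to 157 ± 31.3 RPKM (−2.22 ± 0.31, adjusted p = 0.000108). The succinate dehydrogenase genes sdhC and sdhD fell, with log2 changes of −4.36 and −4.44 (adjusted p = 0.000537 and 2.82e-05).

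Acid resistance genes rose in several systems. Of the 12 genes of the acid fitness island, 9 were higher and 0 lower in KO, and 10 and 0 when adjusted over the list alone (camera adjusted p = 0.000270). Camera gave the acid fitness island an adjusted p = 0.454 with an estimated correlation. Among them, dctR rose by 2.59, mdtF by 1.87, mdtE by 1.74, gadE by 1.30 and hdeA by 0.82 on the log2 scale, the last with an adjusted p of 0.0447. The chaperone gene hdeB (0.76 ± 0.41, adjusted p = 0.142) and hdeD were not called, although limma-voom on recovered reads called hdeB higher (1.13, adjusted p = 0.0399). In the glutamate system, which shares 4 genes with the island, gadE, gadW and gadX were called of 7 (list adjusted p = 0.0115), and 3 when adjusted over the list alone. The glutamate system had an adjusted p = 0.477 with an estimated correlation. The decarboxylase genes gadA (2.49 ± 1.02, adjusted p = 0.0641) and gadB (1.38 ± 0.64, adjusted p = 0.0939) were not called, and their near-identical sequences leave their separate values uncertain. For the arginine, lysine and ornithine systems, 7 of 8 genes were higher over all genes and 7 when adjusted over the list alone, with a median log2 change of 3.13 (camera adjusted p = 6.54e-05). Camera gave the arginine, lysine and ornithine systems an adjusted p = 0.132 with an estimated correlation. They include speF (4.87 ± 0.59, adjusted p = 3.75e-05), cadB, which rose from 11.9 ± 12.4 to 144 ± 122 RPKM, and adiY (4.09 ± 0.59), while adiA was not called. The genes ydeO, ydeP, safA, evgA and evgS rose and phoP and phoQ fell, which was all 7 of the EvgAS, YdeO and PhoPQ list, with the same counts when adjusted over the list alone (camera adjusted p = 0.0146). The EvgAS, YdeO and PhoPQ list had an adjusted p = 0.454 with an estimated correlation. The acid-induced gene asr was not called (0.27 ± 1.06, adjusted p = 0.851).

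Among 33 tested genes listed as H-NS silenced loci, 20 were higher and 1, gspK, was lower over all genes, and 21 and 3 when adjusted over the list alone, with a median log2 change of 2.25 (camera adjusted p = 1.76e-10). Camera gave the silenced loci an adjusted p = 0.132 with an estimated correlation. The bgl operon gene bglG rose by 4.53 on the log2 scale, whereas proV was not called (1.46 ± 0.74, adjusted p = 0.125). All curli genes except csgC were called higher, 6 of 7 both over all genes and when adjusted over the list alone, with csgD rising from 2.60 ± 1.07 to 75.6 ± 9.14 RPKM (camera adjusted p = 1.49e-05). Curli had an adjusted p = 0.0536 with an estimated correlation. The type 1 fimbriae genes fimB, fimE, fimA, fimC and fimD rose, 5 of 9 and 7 when adjusted over the list alone (camera adjusted p = 0.000346). Camera gave type 1 fimbriae an adjusted p = 0.454 with an estimated correlation. Maltose regulon genes rose in 7 of 11 cases over all genes and in 7 when adjusted over the list alone, malK most with a log2 change of 5.73 ± 1.31 (camera adjusted p = 0.000601). The maltose regulon had an adjusted p = 0.470 with an estimated correlation.

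Flagella and chemotaxis genes fell in 17 of 49 cases, with fliC at −1.55, and fliR rose (1 higher and 16 lower when adjusted over the list alone, camera adjusted p = 0.00358), whereas flhD was not called. Camera gave flagella and chemotaxis an adjusted p = 0.454 with an estimated correlation. TCA cycle genes fell in 9 of 15 cases over all genes and in 9 when adjusted over the list alone (camera adjusted p = 0.010). The TCA cycle had an adjusted p = 0.557 with an estimated correlation. Ribosomal protein genes were higher in 8 of 54 cases and in 0 when adjusted over the list alone (camera adjusted p = 0.000542). Camera gave ribosomal proteins an adjusted p = 0.633 with an estimated correlation. Of 25 tested genes of the RpoS-dependent stress response, 7 rose, yciF by 5.75, yciG by 5.42 and yciE by 4.62 on the log2 scale, and uspB fell (−2.21), with the same counts when adjusted over the list alone. The median of this list was −0.01, or 0.13 with the libraries' medians made equal, against a mean of 0.77 (camera, higher, adjusted p = 0.0314). The RpoS-dependent list had an adjusted p = 0.633 with an estimated correlation. The lists of nucleoid-associated proteins, colanic acid, heat shock, envelope stress, the SOS response, ATP synthase, lipopolysaccharide core, cryptic prophages and iron acquisition did not pass camera (camera adjusted p from 0.103 for nucleoid-associated proteins to 0.499 for SOS). In the list of nucleoid-associated proteins hha, stpA, cnu and hupA rose and hns and ihfA fell, so that its median was 0.48 while fry gave a lower direction. Of 22 rRNA genes 4 passed the filter on low values, rrsD, rrsG, rrsH and rrlC, and they were not called.

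In all, 697 of 4436 tested genes were higher and 1203 lower in KO, 616 and 917 of them by at least 2-fold. The libraries of the groups did not overlap for 58.2% of genes, against 10% by chance. The median log2 change of all genes was −0.32, and −0.18 with the libraries' medians made equal, a shift of 0.14 that left 799 higher and 997 lower. The balance depended on the method and its scaling, since limma-voom on reads recovered from the RPKM values called 995 higher and 687 lower, with a median log2 change of 0.04. Called genes lay side by side on the chromosome: 35 runs of at least 5 neighbouring higher genes were found, against a mean of 0.357 and a maximum of 3 in 1000 permutations of the calls. Lower genes formed 41 such runs, against a mean of 4.61 and a maximum of 12. Permuted calls do not keep the genes of an operon together, so the excess is not particular to silenced genes. The run from citT to pagP (645117 to 657117) held 11 genes with a median log2 change of 4.05, and the run from cas2 to sokX (2878569 to 2887411) held 9 with a median of 5.23. Other genes with large increases were ydeI (5.86 ± 0.69), elfA (5.71 ± 0.39) and ybhH (6.60 ± 0.66), and those with large decreases were yjiG (−5.81 ± 0.97), yjiH (−5.20 ± 0.93), msrB (−4.90 ± 0.80), carA (−4.37 ± 0.83), dadA (−4.34 ± 0.31) and glcD (−4.29 ± 1.05).

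**Figure D2:**
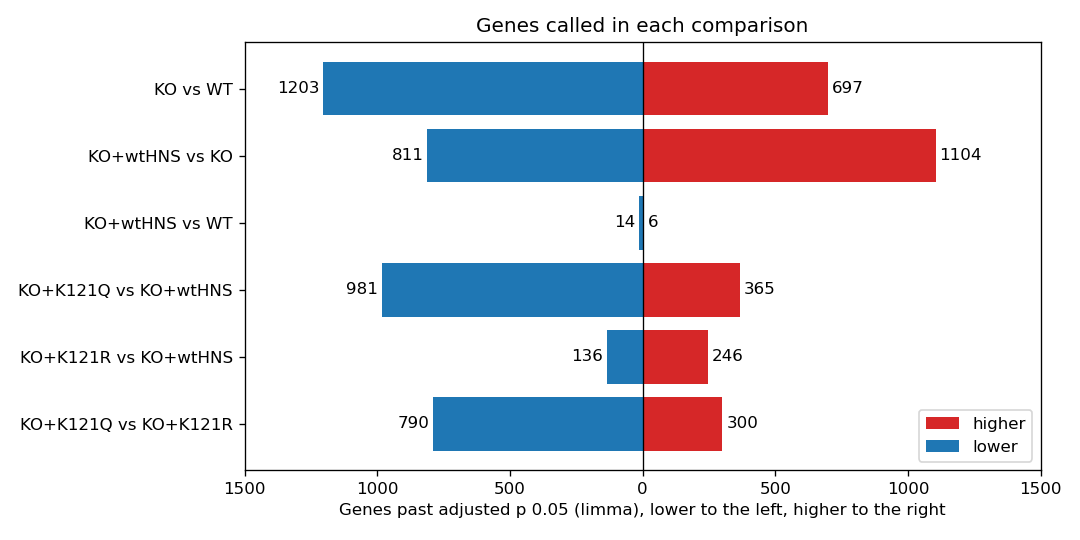
Bars give the number of genes higher (to the right) and lower (to the left) in the first group of each of the 6 comparisons at an adjusted p under 0.05. KO+wtHNS against WT has 6 higher and 14 lower genes, and KO against WT 697 and 1203.

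With wild-type H-NS in the knockout, many of the genes that were high in KO were lower. The genes araA, araB, rhaA and rhaB held 249, 82, 26 and 16 recovered reads over the KO libraries and 0 in KO+wtHNS. This comparison may therefore mix strain background with the added hns gene. The gene casB fell from 639.9 ± 178 to 2.31 ± 3.49 RPKM (log2 change −8.10 ± 0.71, adjusted p = 2.52e-06), stpA from 595 ± 279.8 to 10.6 ± 4.05 RPKM (−5.63 ± 0.43, adjusted p = 8.46e-07) and leuO from 432 ± 53.8 to 13.4 ± 9.72 RPKM (−5.18 ± 0.56, adjusted p = 1.18e-05). The osmoprotectant transporter gene proV fell from 684 ± 260.4 to 66.9 ± 27.2 RPKM (−3.36 ± 0.74, adjusted p = 0.00305), and bglG and hha fell too (−5.48 ± 0.37 and −4.23 ± 0.47). The rpoS transcript rose from 157 ± 31.3 to 719 ± 161 RPKM (2.19 ± 0.31, adjusted p = 9.81e-05), and fliC rose by 1.67. The citrate fermentation genes citD, citF, citE and citX fell, with log2 changes of −8.80, −7.75, −7.54 and −7.37.

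The H-NS silenced loci were lower in 22 of 33 cases and higher in 2, gspK and gspM, both over all genes and when adjusted over the list alone, with a median log2 change of −2.71 (camera adjusted p = 2.27e-09). Camera gave the silenced loci an adjusted p = 0.210 with an estimated correlation. Curli genes were lower in 6 of 7 cases and in 7 when adjusted over the list alone, with csgD at −4.59 ± 0.36 (camera adjusted p = 4.16e-05). Curli had an adjusted p = 0.0710 with an estimated correlation. In the arginine, lysine and ornithine systems potE, speF, adiC, adiY and cadC fell, 5 of 8 with either adjustment (camera adjusted p = 0.00192), whereas cadA and cadB were not called (0.01 ± 0.81 and −0.93 ± 0.77). Camera gave the arginine, lysine and ornithine systems an adjusted p = 0.339 with an estimated correlation. The genes ydeO, ydeP, safA, evgA and evgS fell and phoQ rose, of 7 in their list (2 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.00942). The EvgAS, YdeO and PhoPQ list had an adjusted p = 0.510 with an estimated correlation. Within the acid fitness island dctR, yhiD, mdtE and mdtF fell, 4 of 12 with either adjustment, and the list did not pass (camera adjusted p = 0.0677). The genes gadA, gadB, gadC, gadE, hdeA, hdeB and slp were not called, with log2 changes from −0.89 for gadA to 0.10 for hdeA. Maltose regulon genes fell in 7 of 11 cases and in 8 when adjusted over the list alone, malK with a log2 change of −5.17 (camera adjusted p = 0.00192). Camera gave the maltose regulon an adjusted p = 0.664 with an estimated correlation. Flagella and chemotaxis genes rose in 19 of 49 cases while fliR fell, and in 18 when adjusted over the list alone (camera adjusted p = 0.00247). Flagella and chemotaxis had an adjusted p = 0.614 with an estimated correlation.

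Type 1 fimbriae genes fimB, fimE and fimC fell (3 of 9, 2 when adjusted over the list alone, camera adjusted p = 0.0401), and ribosomal protein genes fell in 7 of 54 cases and in 0 when adjusted over the list alone (camera adjusted p = 0.00869). Camera gave type 1 fimbriae and ribosomal proteins an adjusted p = 0.664 and 0.678 with an estimated correlation. The other lists did not pass camera. Among their members, heat shock genes were higher in 7 of 18 cases with ibpA rising by 2.88, and 9 when adjusted over the list alone (camera adjusted p = 0.0548). The dehydrogenase genes sdhC and sdhD rose by 2.61 and 2.46, with sdhA, sdhB and acnA also higher in the TCA list, 5 of 15 with either adjustment (camera adjusted p = 0.261). RpoS-dependent genes were split, with 8 higher, uspB by 3.36, and treA, yciE, yciF and yciG lower (10 and 4 when adjusted over the list alone). The colanic acid list had a median of 0.02, or −0.05 with the libraries' medians made equal, and a mean of −0.41 (camera, lower, adjusted p = 0.172), with rcsA, gmd, wcaF and wcaE lower. The genes yjiG (5.79 ± 0.97), mtr (5.71 ± 1.05), yjiH (5.42 ± 0.93), pyrI (4.87 ± 1.20, 670.2 ± 718 RPKM in KO+wtHNS), thrA (4.54 ± 0.89) and tabA (4.29 ± 0.38) had large increases.

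In all, 1104 genes were higher and 811 lower in KO+wtHNS than in KO, 852 and 725 by at least 2-fold, and the libraries did not overlap for 52.6% of genes against 10% by chance. The median log2 change of all genes was 0.25, and 0.19 with the libraries' medians made equal. Limma-voom on recovered reads called 735 higher and 1035 lower, with acnA and pyrI no longer among the former (adjusted p = 0.0953 and 0.0605), and without the 19 genes over 1% of reads the calls were 1546 higher and 678 lower. Of the 697 genes higher in KO than in WT, 610 were lower in KO+wtHNS than in KO, and of the 1203 lower genes 874 were higher. Independent lists would share 127.4 and 299.4 genes. Since both comparisons use the KO libraries, part of the excess may come from them. Simulations without group effects gave 0 shared calls, which cannot show how large that part is, because such data leave few calls to share. The simulated covariance across genes was −0.104 against −1.93 in the data.

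KO+wtHNS and WT differed in few genes, 6 higher and 14 lower. The gene tabA (b4252) was at 1635 ± 192 RPKM in KO+wtHNS against 65.5 ± 9.42 in WT (log2 change 4.62 ± 0.38, adjusted p = 4.23e-05), and its neighbour yjgL was also higher (2.55 ± 0.29, adjusted p = 0.000534). The other higher genes were mhpC and mhpD of phenylpropionate degradation (3.21 ± 0.42 and 3.21 ± 0.51), the regulator gene appY (2.63 ± 0.43) and ivy (2.39 ± 0.42). The sugar genes araA (66835 to 68337), araB, rhaA (4094723 to 4095982) and rhaB were listed at 0 in every KO+wtHNS library, against 15.2 ± 7.68, 7.96 ± 4.52, 5.64 ± 1.26 and 7.09 ± 1.42 RPKM in WT (adjusted p = 4.98e-05, 0.000671, 0.000545 and 0.000545). The restriction genes hsdR, hsdM and hsdS were lower, hsdR at 101 ± 40.7 against 394 ± 53.9 RPKM (−2.03 ± 0.30, adjusted p = 0.00401), as were the citrate genes citC, citD, citE, citF and citX (log2 changes from −4.34 for citD to −2.46 for citC), the tRNA gene valX (−5.31 ± 0.75) and the regulator gene lrhA (−1.64 ± 0.28). None of stpA, hha, leuO, bglG, proV, casA, rpoS, csgD and fliC was called, with log2 changes from −1.90 for proV to 0.11 for fliC.

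Several lists were shifted in these libraries although no or 1 member was called over all genes. The RpoS-dependent list had a median log2 change of 1.05 (0 calls over all genes and 2 higher when adjusted over the list alone, camera adjusted p = 2.12e-15). The RpoS-dependent list had an adjusted p = 0.607 with an estimated correlation. The acid fitness island (median 0.69, 0 with either adjustment, camera adjusted p = 2.05e-05) and the glutamate system (median 1.04, 0 with either adjustment, camera adjusted p = 0.000114) were shifted upwards too, with gadA at 1.59 ± 1.02 and slp at 1.39 ± 0.55. Camera gave the acid fitness island and the glutamate system an adjusted p = 0.607 and 0.607 with an estimated correlation. Heat shock genes (median 0.31, camera adjusted p = 0.0106, 0 calls with either adjustment) and type 1 fimbriae (median 0.34, camera adjusted p = 0.00451, 0 calls over all genes and 1 when adjusted over the list alone) were also past the test, with an adjusted p = 0.914 and 0.693 at an estimated correlation. TCA cycle genes were shifted downwards (median −0.79, 0 calls over all genes and 3 lower when adjusted over the list alone, camera adjusted p = 7.08e-05). The TCA cycle had an adjusted p = 0.607 with an estimated correlation. In the H-NS silenced list 1 of 33 genes, appY, was called with either adjustment and the list did not pass (median −0.42, camera adjusted p = 0.353).

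At an unadjusted p under 0.05 limma called 485 genes, and limma-voom called 6 higher and 8 lower after adjustment. Of the lower genes named above it did not call citC, citD, citE, citX, hsdS and valX (adjusted p from 0.0610 for valX to 0.209 for citX), while citF kept its call (adjusted p = 0.0412). The libraries did not overlap for 12.2% of genes, against 10% by chance, and the median log2 change of all genes was −0.11. The counts depended on single libraries: they were 5 and 7 without WT replicate 1, 3 and 8 without WT replicate 2, 40 and 67 without WT replicate 3, 5 and 8 without KO+wtHNS replicate 1, and 9 and 32 without KO+wtHNS replicate 2. The citrate genes were not called without WT replicate 1 or without WT replicate 2.

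In KO+K121Q, part of the silenced genes and the heat shock genes were higher than in KO+wtHNS. The hns transcript was higher as well, so these differences may mix the form of H-NS with the amount of hns transcript. The gene stpA (b2669) was at 619 ± 282 RPKM in KO+K121Q and at 10.6 ± 4.05 RPKM in KO+wtHNS (log2 change 5.71 ± 0.43, adjusted p = 1.30e-05), proV at 694 ± 190.2 and 66.9 ± 27.2 RPKM (3.41 ± 0.74, adjusted p = 0.00511) and the haemolysin gene hlyE at 1250 ± 508 and 57.0 ± 29.9 RPKM (4.51 ± 0.54, adjusted p = 0.000206). The chaperone genes dnaK (3.04 ± 0.69, adjusted p = 0.00655) and htpG (3.42 ± 0.49, adjusted p = 0.000493) were higher. The rpoS transcript was lower, at 178 ± 51.9 against 719 ± 161 RPKM (−2.02 ± 0.31, adjusted p = 0.000683), and fliC was lower too (−2.21 ± 0.27).

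Of 33 genes listed as H-NS silenced loci, 12 were higher, namely leuO, appY, hlyE, stpA, proV, proW, proX and casA to casE, and gspF, gspK, gspL, gspM and chiA were lower (14 and 8 when adjusted over the list alone, camera adjusted p = 0.00133). Camera gave the silenced loci an adjusted p = 0.416 with an estimated correlation. The gene bglG (0.96 ± 0.37, adjusted p = 0.0611), hha (1.17 ± 0.47, adjusted p = 0.0745) and csgD (0.37 ± 0.36, adjusted p = 0.460) were not called, but hha was with the replicate number as a block (adjusted p = 0.0344), and limma-voom called bglG and hha higher (2.39 and 1.60, adjusted p = 0.0351 and 0.0206). Heat shock genes were higher in 13 of 18 cases and in 14 when adjusted over the list alone, with a median of 2.00, or 2.39 with the libraries' medians made equal (camera adjusted p = 1.81e-12). Heat shock had an adjusted p = 0.340 with an estimated correlation. Acid fitness island genes were higher in 6 of 12 cases and in 7 when adjusted over the list alone, among them mdtE (1.91 ± 0.40, adjusted p = 0.00421) and gadE (1.11 ± 0.40, adjusted p = 0.0484, and 0.0523 with the replicate number as a block), while gadA (2.57 ± 1.02, adjusted p = 0.0718), hdeA and slp were not called (list adjusted p = 0.000145). Camera gave the acid fitness island an adjusted p = 0.416 with an estimated correlation. In the glutamate list gadE and gadW were called of 7, and 1 when adjusted over the list alone (camera adjusted p = 0.00196). The glutamate system had an adjusted p = 0.416 with an estimated correlation. The genes speF, adiC, adiA and cadC were higher of 8 in the arginine, lysine and ornithine list with either adjustment (camera adjusted p = 0.00392), and cadA and cadB were not called. Camera gave the arginine, lysine and ornithine systems an adjusted p = 0.416 with an estimated correlation. The acid-induced gene asr was higher (3.21 ± 1.06, adjusted p = 0.0364).

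RpoS-dependent genes treA, yciE, yciF, yciG, osmC and katE were higher and uspB lower of 25, with the same counts when adjusted over the list alone (camera adjusted p = 0.00129). The RpoS-dependent list had an adjusted p = 0.588 with an estimated correlation. The fimbrial genes fimB, fimE and fimC were higher and fimH lower with either adjustment (camera adjusted p = 0.00331), where fimH was no longer called with the libraries' medians made equal. Camera gave type 1 fimbriae an adjusted p = 0.416 with an estimated correlation. Ribosomal protein genes were higher in 10 of 54 cases, 2 when adjusted over the list alone, and 24 with the libraries' medians made equal (camera adjusted p = 3.54e-10). Ribosomal proteins had an adjusted p = 0.426 with an estimated correlation. Lipopolysaccharide core genes waaJ, waaP, waaG and waaQ were higher and waaA lower, the last not called with the libraries' medians made equal (7 and 1 when adjusted over the list alone, camera adjusted p = 0.000145), and the envelope stress genes degP, spy and fkpA were higher with either adjustment (camera adjusted p = 0.0272). Camera gave lipopolysaccharide core and envelope stress an adjusted p = 0.416 and 0.436 with an estimated correlation. In the nucleoid-associated list hns, stpA and ihfB were higher with either adjustment (camera adjusted p = 0.000928). The nucleoid-associated proteins had an adjusted p = 0.258 with an estimated correlation. Flagella and chemotaxis genes were lower in 17 of 49 cases, 20 when adjusted over the list alone and 8 with the libraries' medians made equal (camera adjusted p = 0.000237). Camera gave flagella and chemotaxis an adjusted p = 0.416 with an estimated correlation. The citrate and threonine genes citD (5.89 ± 0.70), citF (4.92 ± 0.52), tdcE (5.09 ± 1.05) and tdcG (4.84 ± 0.99) were higher, and pyrI (−5.07 ± 1.20), mtr (−4.88 ± 1.05), tabA (−4.76 ± 0.38), mhpD (−4.53 ± 0.51) and trpE (−3.72 ± 0.77) were lower. Some of these also separated KO+wtHNS from WT, with citD and citF lower and tabA and mhpD higher in KO+wtHNS. The tabA transcript was at 61.3, 66.2 and 51.3 RPKM in KO+K121Q, 65.5 ± 9.42 in WT and 1635 ± 192 in KO+wtHNS.

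In all, 365 genes were higher and 981 lower in KO+K121Q, 301 and 761 by at least 2-fold, and 43.4% of genes did not overlap against 10% by chance. The median log2 change of all genes was −0.38 and became 0.0046 with the libraries' medians made equal, a shift of 0.38, after which 619 genes were higher and 429 lower. Quantile normalization gave 472 and 485, and limma-voom on recovered reads gave 611 and 413, so the excess of lower genes rests on the scaling. With limma-voom fimH, waaA and pyrI were no longer called (adjusted p = 0.0621, 0.109 and 0.0916). Of the 697 genes higher in KO than in WT, 234 were also higher in KO+K121Q than in KO+wtHNS (57.35 for independent lists) and 15 were lower. Of the 1203 lower genes, 576 were also lower (266 for independent lists) and 9 were higher. Only 429 genes were lower in all with the libraries' medians made equal, so an overlap of 576 rests on the scaling. KO against WT and KO+K121Q against KO+wtHNS share no library, and their log2 changes correlated across genes with r = 0.588, genes not being independent replicates. Calls lay in 8 runs of at least 5 neighbouring higher genes, against a mean of 0.016 and a maximum of 1 in 1000 permutations, with runs at citT to citC, tdcG to tdcB, casE to cas3 and ydhT to ydhY. Lower genes lay in 17 such runs, against a mean of 1.82 and a maximum of 7.

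**Figure D3:**
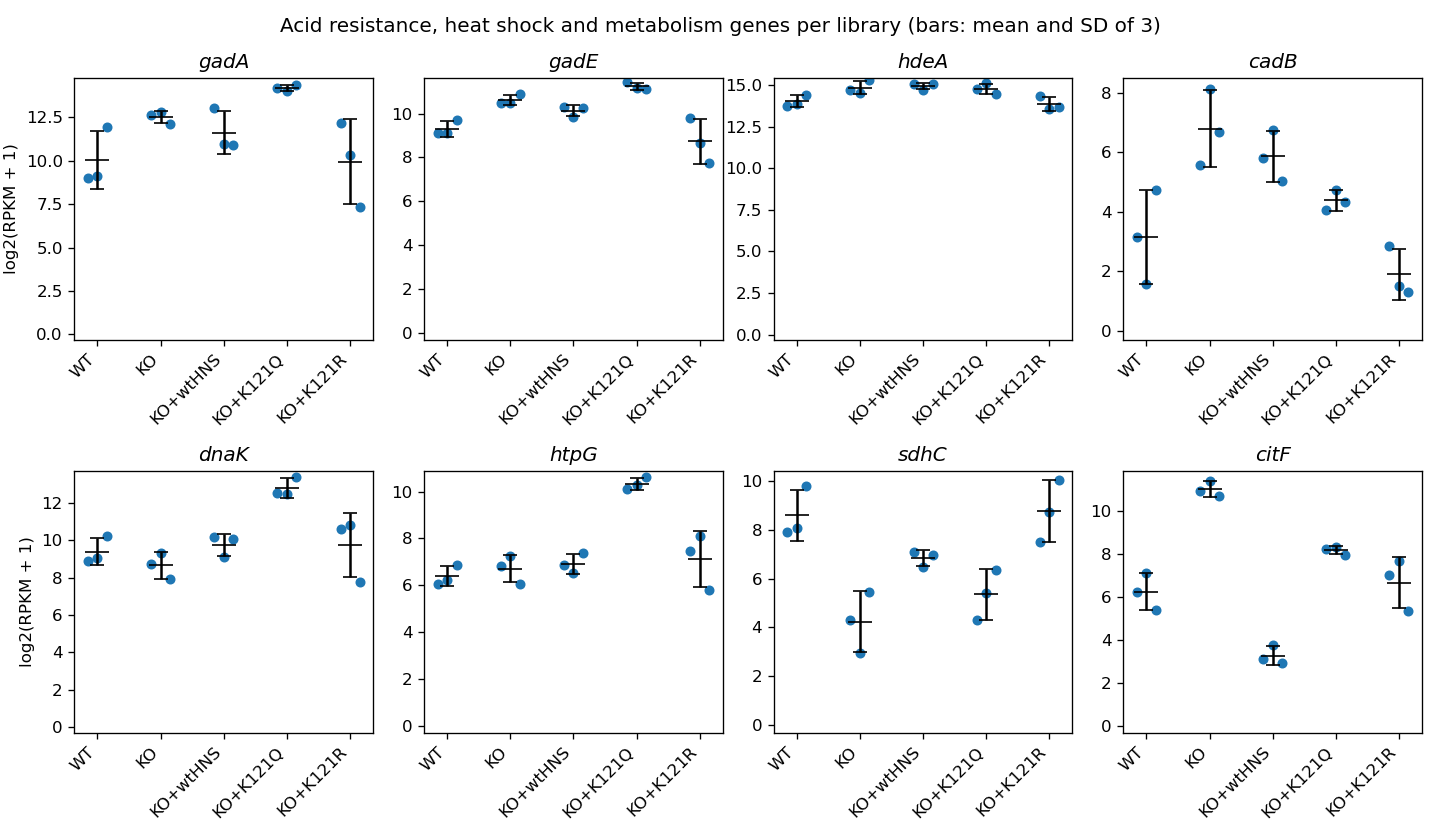
Each point is the log2(RPKM + 1) of 1 library, with the mean and SD of 3 libraries as bars, for 8 acid resistance, heat shock and metabolism genes in the 5 groups. The genes dnaK and htpG are highest in KO+K121Q, and citF is lowest in KO+wtHNS.

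KO+K121R differed from KO+wtHNS in fewer genes, and silenced loci were mostly not among them. The gene stpA was higher in KO+K121R, at 51.2 ± 19.0 against 10.6 ± 4.05 RPKM (log2 change 2.17 ± 0.43, adjusted p = 0.0131), and flhD was higher at 137 ± 43.9 against 36.2 ± 24.2 RPKM (2.02 ± 0.47, adjusted p = 0.0247). The lysine system genes cadA (−3.48 ± 0.81, adjusted p = 0.0252) and cadB (−3.98 ± 0.77, adjusted p = 0.0119) were lower, as were gadE (−1.40 ± 0.40, adjusted p = 0.0438) and hdeA (−1.07 ± 0.31, adjusted p = 0.0468). Against WT, stpA, flhD, cadA, cadB, gadE and hdeA were not called in KO+K121R (adjusted p = 0.127, 0.524, 0.854, 0.349, 0.404 and 0.808). They were not called between KO+wtHNS and WT either (adjusted p from 0.193 for cadA to 0.466 for gadE). The mean of cadA was 39.6 RPKM in WT, 247 in KO+wtHNS and 30.3 in KO+K121R, and that of gadE 650, 1137 and 501 RPKM. In the same order, the mean of flhD was 92.9, 36.2 and 137 RPKM and that of stpA 20.9, 10.6 and 51.2 RPKM. The genes leuO, hha, bglG, proV, csgD and rpoS were not called, with log2 changes from −0.21 for leuO to 0.40 for proV.

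Ribosomal protein genes were higher in 28 of 54 cases and in 47 when adjusted over the list alone, with a median of 1.20 (camera adjusted p = 9.60e-23). Ribosomal proteins had an adjusted p = 0.422 with an estimated correlation. Upward shifts also passed for the TCA cycle, where sdhD and fumA were called (2 of 15, 3 when adjusted over the list alone, camera adjusted p = 0.000182), ATP synthase, where atpE was called (1 of 9, 5 when adjusted over the list alone, camera adjusted p = 0.000546), envelope stress, where degP, fkpA and ppiA were called (3 of 15, 4 when adjusted over the list alone, camera adjusted p = 0.00934), and lipopolysaccharide core, where waaQ was called with either adjustment (camera adjusted p = 0.0375). With an estimated correlation the first 3 of these had an adjusted p = 0.422 and lipopolysaccharide core an adjusted p = 0.494. RpoS-dependent genes bolA, sodC, osmE and uspB were lower (4 of 25, 1 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.000182). Camera gave the RpoS-dependent list an adjusted p = 0.422 with an estimated correlation. The acid fitness island (2 lower of 12, 4 when adjusted over the list alone, camera adjusted p = 0.00186) and the glutamate system, where gadE alone was called (2 when adjusted over the list alone, camera adjusted p = 0.0101), had an adjusted p = 0.422 with an estimated correlation. Flagella and chemotaxis genes had a lower median of −0.65 with flhC and flhD higher and flgL, flhA and cheY lower with either adjustment (camera adjusted p = 0.00151). Flagella and chemotaxis had an adjusted p = 0.422 with an estimated correlation. Type 1 fimbriae, with fimA lower (2 when adjusted over the list alone, camera adjusted p = 0.0197), colanic acid (0 called, camera adjusted p = 0.00667) and cryptic prophages (0 called, camera adjusted p = 0.0280) also passed as lower, each with an adjusted p = 0.422 with an estimated correlation. The H-NS silenced list did not pass, with stpA higher and appY and chiA lower with either adjustment (camera adjusted p = 0.172). In KO+wtHNS against WT the RpoS-dependent, acid fitness island, glutamate and type 1 fimbriae lists were shifted upwards and the TCA cycle downwards. Their opposite shifts here may therefore lie in KO+wtHNS rather than in KO+K121R. Against WT limma called 0 genes in KO+K121R, although the ribosomal protein list was shifted upwards there too.

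In all, 246 genes were higher and 136 lower in KO+K121R, 197 and 116 by at least 2-fold, and 24.7% of genes did not overlap against 10% by chance. Several of the largest differences were genes that also separated KO+wtHNS from WT: valX (5.82 ± 0.75), citD (4.88 ± 0.70), tabA (−5.01 ± 0.38), mhpC (−3.53 ± 0.42) and mhpD (−3.58 ± 0.51), and araA, which was listed at 0 in KO+wtHNS and at 11.8 ± 2.71 RPKM in KO+K121R. With only the 6 libraries compared in the fit the calls were 3 higher and 4 lower. The split depended on abundant genes, with 114 higher and 260 lower once the 19 genes over 1% of reads were left out. It depended on single libraries too: the calls were 60 and 48 without KO+wtHNS replicate 1, 172 and 73 without KO+wtHNS replicate 2, 336 and 337 without KO+K121R replicate 1, 54 and 17 without KO+K121R replicate 2, and 79 and 26 without KO+K121R replicate 3. Among the genes no longer called without KO+K121R replicate 2 were cadA, cadB, gadE, hdeA, flhD and fimA. Limma-voom did not call hdeA and cheY (adjusted p = 0.0520 and 0.0613). Of the 697 genes higher in KO than in WT, 80 were also higher in KO+K121R (38.65 for independent lists) and 15 lower, and of the 1203 lower genes 57 were also lower (36.88 for independent lists) and 20 higher, with r = 0.159 across genes. Over the 697 genes the median log2 change in KO+K121R against KO+wtHNS was 0.02, and 50.8% changed upwards. Over the 1203 genes it was −0.26, and 66.6% changed downwards, while the median of all genes was −0.10.

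KO+K121Q and KO+K121R were also compared directly. Many acid resistance and heat shock genes and part of the silenced genes were higher in KO+K121Q. The hns transcript was higher as well, at 14190 ± 2620 RPKM in KO+K121Q and 4384 ± 1110 RPKM in KO+K121R. Differences between these groups may therefore mix the form of H-NS with the amount of hns transcript. The gene gadE was at 2432 ± 266 RPKM in KO+K121Q and 501 ± 346 RPKM in KO+K121R (log2 change 2.51 ± 0.40, adjusted p = 0.00113), adiA at 372 ± 364 and 29.5 ± 21.6 RPKM (3.18 ± 0.83, adjusted p = 0.0147), and stpA at 619 ± 282 and 51.2 ± 19.0 RPKM (3.54 ± 0.43, adjusted p = 0.000289). The master flagellar regulator gene flhD was lower, at 19.4 ± 12.7 against 137 ± 43.9 RPKM (−2.88 ± 0.47, adjusted p = 0.00139), as were rpoS (−1.98 ± 0.31, adjusted p = 0.00107) and sdhC (−3.40 ± 0.75, adjusted p = 0.00655).

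All 12 acid fitness island genes except hdeB were higher, and 12 when adjusted over the list alone, with a median of 2.02 (camera adjusted p = 5.04e-11). Camera gave the acid fitness island an adjusted p = 0.134 with an estimated correlation. In the glutamate system 6 of 7 genes were higher with either adjustment, gadA by 4.24, gadB by 2.58 and gadC by 2.41 (camera adjusted p = 3.77e-07). The glutamate system had an adjusted p = 0.134 with an estimated correlation. For arginine, lysine and ornithine, 6 of 8 were higher and 8 when adjusted over the list alone, adiC by 3.88 and cadB by 2.49 (camera adjusted p = 3.77e-07). Camera gave the arginine, lysine and ornithine systems an adjusted p = 0.106 with an estimated correlation. Heat shock genes were higher in 14 of 18 cases and in 16 when adjusted over the list alone, dnaK by 3.08 and clpB by 3.13 (camera adjusted p = 4.03e-14). Heat shock had an adjusted p = 0.134 with an estimated correlation. RpoS-dependent genes were higher in 11 of 25 cases and in 14 when adjusted over the list alone, yciG by 5.41 and katE by 1.96 (camera adjusted p = 5.83e-13). Camera gave the RpoS-dependent list an adjusted p = 0.160 with an estimated correlation. Of the H-NS silenced loci 13 of 33 were higher, among them casB (4.02 ± 0.71), appY (4.41 ± 0.43), proW (3.72 ± 0.77) and leuO (2.03 ± 0.56), and gspF, gspK and gspL were lower (16 and 5 when adjusted over the list alone, 16 and 1 with the libraries' medians made equal, camera adjusted p = 2.41e-06). The silenced loci had an adjusted p = 0.160 with an estimated correlation. The fimbrial genes fimB, fimE, fimA, fimI and fimC were higher, 6 of 9 when adjusted over the list alone (camera adjusted p = 1.40e-06). Camera gave type 1 fimbriae an adjusted p = 0.149 with an estimated correlation. The genes bglG, hha, ydeO, evgA, asr, tmcA and csgD were not called (log2 changes from 0.04 for evgA to 1.59 for asr), although limma-voom called bglG, hha and hdeB higher (2.43, 1.42 and 1.27, adjusted p = 0.0435, 0.0453 and 0.0461).

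TCA cycle genes were lower in 13 of 15 cases with either adjustment, and in 9 with the libraries' medians made equal, with gltA at −2.60 and sdhD at −2.94 (camera adjusted p = 8.07e-06). The TCA cycle had an adjusted p = 0.230 with an estimated correlation. ATP synthase genes atpE, atpB and atpI were lower, 7 of 9 when adjusted over the list alone and 1 with the libraries' medians made equal (camera adjusted p = 0.00995). Camera gave ATP synthase an adjusted p = 0.420 with an estimated correlation. Ribosomal protein genes rpmI, rpsM, rplJ and rplL were lower, 0 of 54 when adjusted over the list alone and 0 with the libraries' medians made equal (camera adjusted p = 0.0197). Ribosomal proteins had an adjusted p = 0.721 with an estimated correlation. In lists shifted upwards dps, hns and stpA of the nucleoid-associated proteins (3 when adjusted over the list alone, camera adjusted p = 0.000359) and rcsA, wcaF and wcaE of colanic acid, where wcaL was lower but not with the libraries' medians made equal (3 and 0 when adjusted over the list alone, camera adjusted p = 0.0197), were called. Camera gave the nucleoid-associated proteins and colanic acid an adjusted p = 0.106 and 0.403 with an estimated correlation. The lipopolysaccharide core (median 0.48, waaA lower with either adjustment, camera adjusted p = 0.00654) and cryptic prophages (median 0.09, 0 called, camera adjusted p = 0.0282) passed as higher, both with an adjusted p = 0.420 with an estimated correlation. Iron acquisition did not pass, with fhuA, fhuC, entF and cirA lower, and its median of −0.33 became 0.05 with the libraries' medians made equal (camera adjusted p = 0.742). The SOS list did not pass either, with ruvA and ruvB lower, a median of −0.0019 (0.38 with the libraries' medians made equal, when neither was lower) and a mean of 0.02 (camera, higher, adjusted p = 0.188, and fry, lower).

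In all, 300 genes were higher and 790 lower in KO+K121Q than in KO+K121R, 285 and 541 by at least 2-fold, and 41.8% of genes did not overlap against 10% by chance. The median log2 change of all genes was −0.35 and became 0.03 with the libraries' medians made equal, after which 467 genes were higher and 275 lower. Quantile normalization gave 345 and 334, and limma-voom gave 433 and 266. With limma-voom atpE, atpB, gspF, gspK, wcaL, fhuA, fhuC, entF, cirA, ruvA, ruvB, rpmI, rpsM, rplJ and rplL were no longer called lower, nor cadB higher (adjusted p = 0.0576). The counts were 216 and 503 without KO+K121Q replicate 1, 190 and 442 without KO+K121Q replicate 2, and 222 and 488 without KO+K121R replicate 3. Of the 697 genes higher in KO than in WT, 190 were also higher in KO+K121Q than in KO+K121R (47.14 for independent lists), and of the 1203 lower genes 392 were also lower (214.2 for independent lists), with no library in common and r = 0.497 across genes. Only 275 genes were lower in all with the libraries' medians made equal, so an overlap of 392 rests on the scaling. Other genes far apart were ydeI (5.18 ± 0.69), elfA (4.89 ± 0.39), yhiM (4.54 ± 1.06), hlyE (4.45 ± 0.54), yjiH (−3.90 ± 0.93), yjiG (−3.70 ± 0.97) and fdoI (−3.54 ± 0.54). With an estimated correlation between genes, camera called no list in any of the 6 comparisons. On simulated data it called 20 of 20 lists of 20 genes changed 2-fold. The simulated genes varied independently, so this does not show how camera handles lists of genes that move together.

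**Figure D4:**
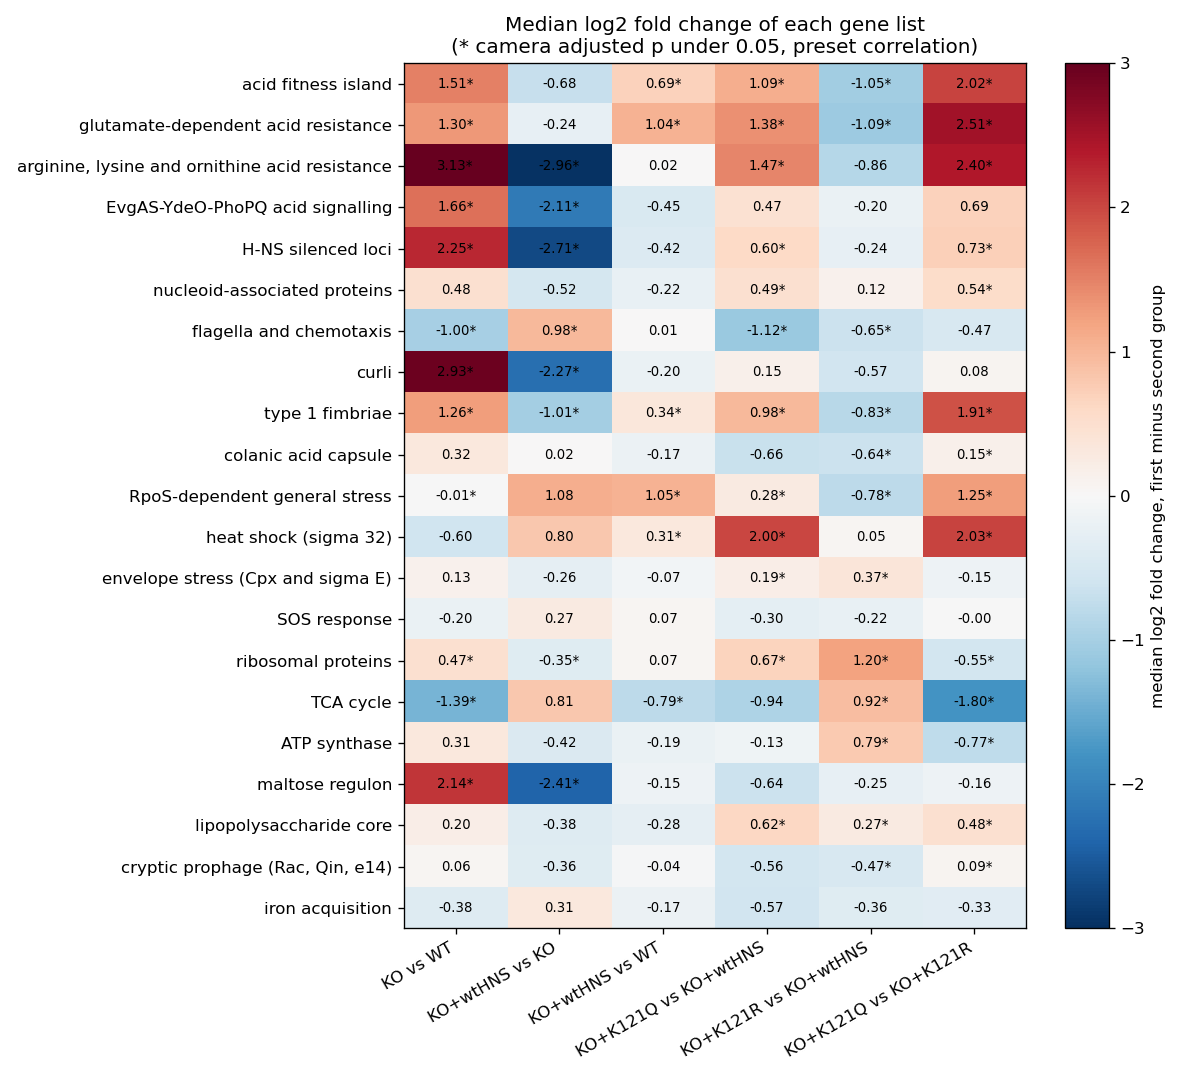
Each cell gives the median log2 change of a gene list (rows) in 1 of the 6 comparisons (columns), coloured from −3 to 3, with a star where camera's adjusted p is under 0.05 at the preset correlation. Heat shock medians are 2.00 and 2.03 in KO+K121Q against KO+wtHNS and KO+K121R, and curli medians are 2.93 in KO against WT and −2.27 in KO+wtHNS against KO.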

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

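Limma-voom on recovered reads, median scaling and WT as the reference were chosen after the results were seen. In the 6 comparisons, with all libraries kept, the number of genes called, higher and lower in turn, moved by more than 1.5 times in the following cases. Where nothing else is said the cause was not tested. With only the 6 libraries compared, which leaves fewer samples to estimate the spread, KO+wtHNS against WT had 3 and 3 calls, KO+K121R against KO+wtHNS 3 and 4, and the lower calls of KO+K121Q were 617 against KO+wtHNS and 522 against KO+K121R. With quantile normalization the lower calls of KO+K121Q were 485 against KO+wtHNS and 334 against KO+K121R. Without the genes over 1% of reads KO+K121R against KO+wtHNS had 114 and 260. With limma-voom, which also scales the libraries in another way, the lower calls were 687 in KO against WT, 8 in KO+wtHNS against WT, 413 in KO+K121Q against KO+wtHNS and 266 in KO+K121Q against KO+K121R, and the higher calls 735 in KO+wtHNS against KO and 611 in KO+K121Q against KO+wtHNS. With median scaling KO+K121Q had 619 and 429 calls against KO+wtHNS and 467 and 275 against KO+K121R, which follows from the lower median of its libraries. With WT as the reference KO+K121R had 0 and 0 calls, with 982 genes at an unadjusted p under 0.05 and 107 and 37 by limma-voom. Among the 4 added comparisons, quantile normalization gave 487 higher genes in KO+K121Q against KO, and 472 and 527 calls in KO+K121Q against WT. Limma-voom gave 611 and 460 in KO+K121Q against WT. Calls of at least 2-fold left 540 higher genes in KO+K121R against KO.

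With the replicate number as a block (replicate block) the calls were 708 and 1221 for KO against WT, 1110 and 823 for KO+wtHNS against KO, 6 and 14 for KO+wtHNS against WT, 391 and 988 for KO+K121Q against KO+wtHNS, 293 and 150 for KO+K121R against KO+wtHNS, and 317 and 804 for KO+K121Q against KO+K121R. In the added comparisons it had 70 and 29 calls for KO+K121R against WT, where none were called without it, and 872 and 699 for KO+K121R against KO. Of the named genes 6 in the 6 comparisons and asr in KO+K121Q against KO were no longer called or became called with it: fimC, hsdS, gadE, hha, entF and wcaL. Whether the numbers pair the libraries is not settled: residual correlations of the 30 pairs with the same number ran from −0.257 to 0.326 with a median of 0.0409, 10 were over 0.1, and 6 of 15 libraries correlated best with their own number. All 3 pairs were over 0.1 in 2 of 10 pairs of groups, and in 3 of 50 matchings with crossed numbers. The mean of the 30 was 0.0425, and 120 of 1296 renumberings gave a mean as high.

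Leaving out 1 library at a time gave 585 to 626 higher and 859 to 1104 lower genes in KO against WT, 826 to 1025 and 652 to 822 in KO+wtHNS against KO, 3 to 40 and 7 to 67 in KO+wtHNS against WT, 253 to 351 and 663 to 928 in KO+K121Q against KO+wtHNS, 54 to 336 and 17 to 337 in KO+K121R against KO+wtHNS, and 190 to 362 and 442 to 697 in KO+K121Q against KO+K121R. Fewer samples explain lower counts in part, whereas counts that rose point to the library left out: WT replicate 3 or KO+wtHNS replicate 2 (9 and 32) for KO+wtHNS against WT, and KO+K121R replicate 1 or, for higher calls only, KO+wtHNS replicate 3 (268) for KO+K121R against KO+wtHNS. Smaller rises were 362 higher in KO+K121Q against KO+K121R without KO+K121R replicate 1 and 822 lower in KO+wtHNS against KO without KO+wtHNS replicate 2.

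Camera called 0 lists as higher and 0 as lower in each of the 6 comparisons with an estimated correlation, which allows for genes of a list moving together. With only the 6 libraries compared it called 2 lists as higher in KO+wtHNS against KO and 2 as lower in KO+K121Q against KO+wtHNS, and with quantile normalization 3 and 3 in KO+K121R against KO+wtHNS. Leaving out 1 library gave 9 to 11 higher and 2 lower lists in KO against WT, 1 to 2 and 6 to 8 in KO+wtHNS against KO, 4 to 5 and 1 to 3 in KO+wtHNS against WT, 10 to 11 and 1 to 2 in KO+K121Q against KO+wtHNS, 3 to 5 and 5 to 7 in KO+K121R against KO+wtHNS, and 8 to 11 and 1 to 3 in KO+K121Q against KO+K121R.

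Of 384 log2 changes of named genes, 248 kept their direction and their side of the threshold under every alternative, and 264 did so under those that keep all libraries of the comparison. Under 1 or more of the latter 106 were no longer called (66 with only the 6 libraries compared) and 12 became called. Without 1 of the libraries 82 were no longer called. With WT as the reference 2 reversed: cadA in KO+K121Q had a log2 change of 2.31, and araA in KO+K121R one of −0.26, which follows from araA being listed at 0 in KO+wtHNS. The alternatives edgeR with RLE factors, edgeR with upper-quartile factors and DESeq2 were not run, because the values are RPKM and not counts. At 3134802 to 3966168 assigned reads per library, changes of 2-fold were recovered in 27 to 31% of simulated genes, so a gene not called is not shown to be unchanged, least of all one near 0 reads.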

Other observations

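The 4 comparisons of KO+K121Q and KO+K121R with KO and WT, the tests of the 3 patterns and the counts for other splits of the libraries were chosen after the results were seen. Many silenced genes were lower than in KO: bglG (log2 change −4.53 ± 0.36, adjusted p = 5.12e-06), leuO (−3.36 ± 0.56, adjusted p = 0.000897), hha (−3.06 ± 0.47, adjusted p = 0.000569) and csgD (−4.22 ± 0.36, adjusted p = 9.67e-06) were lower in KO+K121Q. Of the 33 silenced loci 21 were lower and appY was higher (23 and 1 when adjusted over the list alone, camera adjusted p = 7.13e-09), and all 7 curli genes were lower with either adjustment (camera adjusted p = 3.52e-07). The silenced loci and curli had an adjusted p = 0.173 and 0.0235 with an estimated correlation. In contrast stpA (0.08 ± 0.43, adjusted p = 0.920), proV (0.05 ± 0.74, adjusted p = 0.974) and rpoS (0.17 ± 0.31, adjusted p = 0.748) were not called different from KO. Heat shock genes were higher than in KO in 16 of 18 cases and in 18 when adjusted over the list alone, clpB by 4.37, dnaK by 4.14 and htpG by 3.62 (camera adjusted p = 4.57e-20). Camera gave heat shock an adjusted p = 0.106 with an estimated correlation. The maltose genes malK (−5.58 ± 1.31), lamB (−4.82 ± 1.37) and malM (−4.75 ± 1.16) were lower, and asr was higher (3.33 ± 1.06, adjusted p = 0.0409). Limma-voom did not call lamB, at 285 ± 411 RPKM in KO+K121Q, or asr (adjusted p = 0.0614 and 0.0641). In all, 234 genes were higher and 670 lower than in KO, and 532 and 480 with the libraries' medians made equal, a shift of 0.32 in the median of all genes. The counts were 127 and 516 without KO replicate 1, 118 and 489 without KO+K121Q replicate 1, and 129 and 500 without KO+K121Q replicate 3, and asr was not called in any of these 3 cases.

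In KO+K121R the genes casB (−7.72 ± 0.71, adjusted p = 4.10e-06), leuO (−5.39 ± 0.56), bglG (−5.49 ± 0.36), stpA (−3.46 ± 0.43, adjusted p = 4.08e-05) and proV (−2.95 ± 0.74, adjusted p = 0.00794) were lower than in KO, and 25 of 33 silenced loci were lower and gspK higher (26 and 1 when adjusted over the list alone, camera adjusted p = 4.29e-14). The silenced loci had an adjusted p = 0.0694 with an estimated correlation. The curli list was lower in all 7 genes with either adjustment (camera adjusted p = 6.48e-07). Camera gave curli an adjusted p = 0.0246 with an estimated correlation. The genes sdhC (4.52 ± 0.74), sdhD (4.53 ± 0.51) and rpoS (2.14 ± 0.31, adjusted p = 0.000139) were higher, as were 9 of 15 TCA cycle genes with either adjustment (camera adjusted p = 0.00117). The TCA cycle had an adjusted p = 0.429 with an estimated correlation. The lysine and arginine genes cadB (−4.91 ± 0.77), adiC (−3.98 ± 0.88) and cadA (−3.47 ± 0.81) were lower. In all, 847 genes were higher and 693 lower than in KO, and 463 and 812 with limma-voom, which did not call gspK. Without KO replicate 1 they were 535 and 597, and without KO replicate 2 they were 547 and 609.

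Between KO+K121R and WT limma called 0 genes, with 982 at an unadjusted p under 0.05, while limma-voom called 107 higher and 37 lower. The count of 0 depended on the fit and on 1 library: it was 70 higher and 29 lower with the replicate number as a block, and 143 and 134 without KO+K121R replicate 1. Among the genes not called were stpA (1.25 ± 0.43, adjusted p = 0.127), leuO (−0.63 ± 0.56), rpoS (−0.08 ± 0.31) and gadA (−0.08 ± 1.02). The ribosomal protein list was shifted upwards (median 1.15, 0 calls over all genes and 46 higher when adjusted over the list alone, camera adjusted p = 1.10e-36). Camera gave ribosomal proteins an adjusted p = 0.494 with an estimated correlation.

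Between KO+K121Q and WT 311 genes were higher and 1283 lower, and 571 and 469 with the libraries' medians made equal, a shift of 0.46 in the median of all genes. The counts were 207 and 762 without WT replicate 1 and 224 and 842 without WT replicate 2. The genes stpA (4.79 ± 0.43, adjusted p = 3.07e-05), gadA (4.16 ± 1.02, adjusted p = 0.00831), gadB (2.65 ± 0.64), gadE (1.93 ± 0.40), slp (2.12 ± 0.55) and asr (3.60 ± 1.06, adjusted p = 0.0196) were higher, and rpoS (−2.06 ± 0.31), flhD (−2.34 ± 0.47) and fliC (−2.10 ± 0.27) were lower. All 7 glutamate system genes were higher with either adjustment (camera adjusted p = 4.41e-07), as were 14 of 18 heat shock genes, 16 when adjusted over the list alone (camera adjusted p = 1.55e-16). The glutamate system and heat shock had an adjusted p = 0.142 and 0.132 with an estimated correlation. The silenced loci were split into 9 higher and 9 lower of 33 (10 and 10 when adjusted over the list alone), with a median of −0.0014, a mean of 0.45 and a median of 0.45 with the libraries' medians made equal (camera, higher, adjusted p = 0.00379). Camera gave the silenced loci an adjusted p = 0.354 with an estimated correlation.

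The genes araB, araA, rhaB and rhaA had 0 recovered reads in the 3 KO+wtHNS libraries. At the lowest rate of the other 12 libraries 192 reads would be expected, which argues against counting chance, and the WT and KO+K121R libraries, which also express hns, held 981 reads, which argues against silencing by H-NS. A strain background of KO+wtHNS that lacks these genes and part of lacZ stays open. The highest ratio of lacZ to lacY reads in KO+wtHNS was 2.17 and the lowest in the other 12 libraries 4.43, a quotient of 0.489. This decides nothing, because the low lacZ was seen before that explanation was written and the KO+wtHNS libraries hold only 6 to 11 reads of lacY. Reads of araD (163, of which 143 in 1 library) and rhaD (8) remained, so any loss does not cover them whole. Differences between KO+wtHNS and the other 4 groups may mix strain background with the form of H-NS, and the labels do not settle it.

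The silenced loci leuO, appY, hlyE, stpA, proV, proW, proX and casA to casE were higher in KO+K121Q than in KO+wtHNS. The genes casA to casE lie side by side on the chromosome, as do proV and proW, so the 12 genes are not independent loci. A background of KO+wtHNS alone is argued against, since all 12 were also higher in KO+K121Q than in KO+K121R, with a median log2 change of 3.19. The KO+K121Q libraries also served to choose the 12, so part of this agreement may come from those libraries. Against WT 8 of the 12 were higher, with a median of 1.87, while leuO (1.40, adjusted p = 0.0637), proV (1.51, adjusted p = 0.127), proW (1.72, adjusted p = 0.0969) and proX (1.80, adjusted p = 0.0927) were not called. Less hns transcript is argued against because hns was higher in KO+K121Q by 1.88, and scaling between libraries because the median of the whole list was 0.98 with the libraries' medians made equal. For the 8 genes higher than in each of the 3 other groups that express hns, the cause was not tested, since transcript levels do not show where H-NS binds. Weaker silencing by the K121Q form is 1 hypothesis, which measuring H-NS protein and its binding at these loci in the same strains would decide. Against WT leuO was higher with limma-voom (1.96, adjusted p = 0.0117), and proV, proW and proX were not called by it either (adjusted p = 0.0776, 0.0616 and 0.0657), which leaves their difference from WT open. A strain background of KO+K121Q, the amount of H-NS protein and the acetylation of the protein were not tested, and stpA itself, being a paralog of H-NS, may act on the same genes.

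WT replicate 3 stood apart from the other 2 WT libraries, with correlations of 0.946 and 0.950 to them against 0.982 between them, and without it KO+wtHNS against WT had 40 higher and 67 lower genes. It correlated better with KO+K121R replicate 1 (0.967) and with KO+wtHNS replicates 1 and 2 (0.961 and 0.960) than with either WT library. A KO+wtHNS library under a WT label is nevertheless argued against by 295 reads of araB, araA, rhaB and rhaA, and a KO library by 8201 reads of hns. A KO+K121R library under a WT label is not argued against: over the 100 genes with the lowest p between the other WT libraries and KO+K121R, chosen without it, WT replicate 3 lay at 0.581 on a scale from 0 (WT) to 1 (KO+K121R). The KO+K121R libraries left out in the same way lay at 0.425 to 0.711, and WT replicates 1 and 2, each set against WT libraries that included replicate 3, at 0.00186 and 0.286. The mean correlation with the 3 KO+K121R libraries minus that with the other WT libraries was −0.00465. The rhaB reads go the other way, 46 in WT replicate 3, 42 and 30 in the other WT libraries and 19, 10 and 16 in KO+K121R. So does hsdR, at 347 RPKM in WT replicate 3, 453 and 381 in the other WT libraries and 291, 180 and 273 in KO+K121R. The ratio of lacZ to lacY reads was 5.57, against 4.43 and 8.8 in WT and 11.5, 13.4 and 11.6 in KO+K121R. These are single genes picked after their values were seen, and rhaB and lacY hold few reads. A difference in growth or acid exposure of that culture might place it between the groups as well and was not tested, so its label stays open.

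With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split gave 1900 calls for KO against WT (highest of the other splits 1), 1915 for KO+wtHNS against KO (1), 1346 for KO+K121Q against KO+wtHNS (1), 382 for KO+K121R against KO+wtHNS (5) and 1090 for KO+K121Q against KO+K121R (0). For KO+wtHNS against WT the real split gave 20, and 1 other split, with WT replicates 1 and 2 and KO+wtHNS replicate 2 on 1 side, gave 22, so 2 splits reached the real count. For KO+K121Q against KO+wtHNS, whose same-number libraries deviated together, the 3 other splits that part every number gave 0 calls, and the remaining 6 splits part only 1 number.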
